A study of uncultured bacterium with 48 samples.

How the data were processed

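DNA was extracted from soil of 48 BioCON grassland plots sampled in August 2009, labelled with Cy5 by random priming and hybridised to GeoChip, 1 array per plot, per the labels. The 4 groups (aCaN, eCaN, aCeN and eCeN) hold 12 arrays each and were taken from the sample labels alone.

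The raw table holds the intensity of each probe as deposited by the authors, on a linear scale and blank where a probe was not detected. Its usable values run from 1091 to 805579. Whether arrays had been scaled to one another, and how background was corrected and detection called, is not stated in the labels. Background values were not used here. The processed table holds a score made by the authors: over its first 40098 data lines it is the natural log of the raw signal divided by the array's mean natural log (9.29 to 9.82), kept per group where at least 4 of 12 arrays had a value. This was tested on the files, with 1265376 of 1265377 matched values within a relative 0.0001.

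The lines of the processed table are displaced against their probe names. Of 35305 lines with a score, all were matched in order to a raw line, and 274 stood at the line of their own name. The median displacement was 77 lines. A further 5390 lines held 20132 values identical to the raw signal. The processed table had been chosen as the source of the main values before the data were examined, and was replaced by the raw table because of this displacement. Its scores, put back on the lines they matched, served as an alternative. Over the first 40098 lines of the processed table, the tables also differ in which arrays they call eCaN and aCeN. The 20132 identical values all stood under the same column name in both. The names of the raw table were used, with the exchange as an alternative. In both tables a last block of 13691 lines, in 11481 of which lineage text stands in a sample column, holds values on another scale in 8 columns and was not used.

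Probes were summed per gene family, process list and taxon on the linear scale, with a probe not detected counted as 0, and the totals taken as log2. Of 485 families, 366 with at least 3 probes and a signal in every array were tested, and 119 were left out (78 with fewer than 3 probes and 90 with no signal in at least 1 array, some for both reasons). For single probes, 26030 with a value in at least 6 of 12 arrays of every group were tested on log2 signal. The 25 lists were starch, hemicellulose, cellulose, chitin, pectin, and aromatic and lignin degradation, carbon fixation, methane cycling, nitrogen fixation, nitrification, denitrification, ammonification and urea hydrolysis, assimilatory nitrate reduction, dissimilatory nitrate reduction to ammonium, anammox, phosphorus cycling, sulfur cycling, the nitrogen and carbon, phosphate, and oxidative and osmotic stress responses, antibiotic resistance transporters, and fungi, archaea, bacteria and bacteriophage. Antibiotic resistance transporters also hold the B_lactamase and Van families, and aromatic and lignin degradation also holds AceA, AceB, LMO, limEH and camDCAB. The 39 taxa were 36 phyla, the domains Bacteria and Archaea, and the fungi, as named in the files. No gene identifier or genome position was used.

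Groups were compared with limma 3.58.1 (lmFit and eBayes, 1 mean per group, no covariate) in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment over all features of a kind and a threshold of 0.05. Beside it, p-values of list members and of the panel were adjusted over the list alone. The 5 planned comparisons were CO2 at each N level, N at each CO2 level and their interaction. The comparison of eCeN with aCaN and those of each factor over both levels of the other were added after the data had been examined. Detected probes and log2 total signal were compared by permutation tests with 100000 resamples, two-sided, in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. The interaction was tested by permuting residuals of the additive model. Composition was compared with PERMANOVA (vegan 2.7.1, 99999 permutations, Bray-Curtis distance), and detection of single probes with Fisher's exact test. Figures were drawn with matplotlib 3.10.9.

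Named families were fixed by rule: those past the threshold, or, where fewer than 5 passed, the 5 with the smallest p, and in every comparison a panel of 24 families of carbon, nitrogen, phosphorus, sulfur and methane cycling, of which 23 were present and soxY was not. Of probes, the 3 with the smallest p per comparison were named by family and organism. Other names, such as list members nearest to the threshold, taxa and families that differ between array numbers, were chosen after their values were seen.

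Other settings chosen beforehand were relative abundance, 1 total per array, quantile normalization, the mean log2 signal of detected probes, other filters on probes and families, a pseudocount of 1% of the median family total (4171), a trended and robust prior, missing values set to the lowest signal, the replicate number as a block, other distances, and leaving out each of the 48 arrays in turn. Added after the data had been examined were the processed values put back on their lines, the exchanged names, quantile normalization for lists, 1 total per array, quantile normalization and means of detected probes for taxa, leaving out arrays numbered 10 to 12 and a term for them. Also added then were a block for each number within an N level (24 blocks of 2 arrays, for CO2 and the interaction), means of those 2 arrays (for pooled N), each also with 1 total per array, quantile normalization and means of detected probes, and permutations of array values within or of those blocks. A background correction with normexp was not run, for want of background values. Other splits of the arrays, exchanges within blocks and orders of the array numbers were drawn 100 times each with a fixed seed, the real one included. In each order of the numbers the choice of 3 numbers with the most families, of all 220, was taken. The calls were tested on simulated data, with known folds planted in shuffled arrays in 20 runs. For arrays no counting depth exists, and the number of independent arrays sets the precision.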

Results

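Soil DNA from grassland plots of the BioCON field experiment was hybridised to GeoChip, a microarray whose probes each stand for a gene of a named functional family from a named organism. The 48 arrays fell into 4 groups of 12 plots each, named by CO2 and nitrogen (N) level: aCaN (ambient CO2, ambient N), eCaN (enriched CO2, ambient N), aCeN (ambient CO2, enriched N) and eCeN (both enriched). The deposited signals covered 45488 probes of 485 gene families. A single array detected between 20760 and 31546 probes and had a log2 total signal between 28.81 and 29.02, and 8515 probes were detected in all 48 arrays. Detected probes averaged 26800 ± 3416 (SD, n = 12) in aCaN, 28120 ± 1581 in eCaN, 27286 ± 1854 in aCeN and 28087 ± 1688 in eCeN. The number of arrays limits the precision: with arrays taken as independent, the median 95% confidence interval of a family's difference between 2 groups reached 10.5% to either side. The labels do not say whether plots of a group share a ring. If they do, the independent units are fewer and the intervals too narrow.

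**Figure D1:**
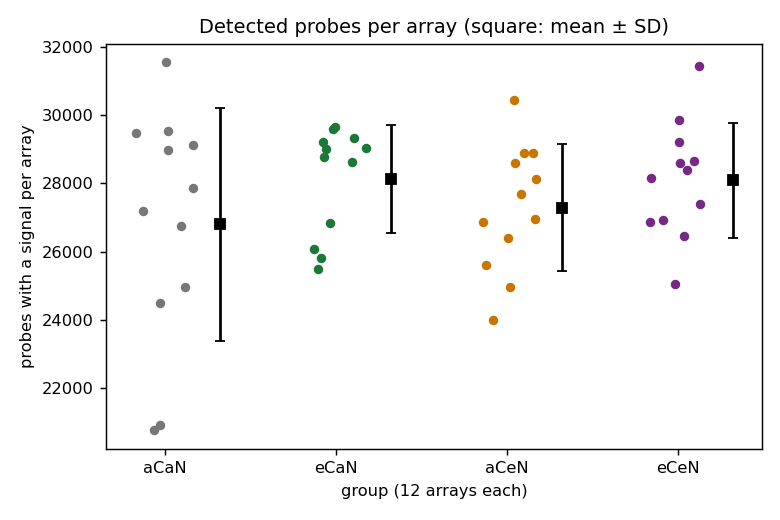
Number of detected probes (vertical axis) of each of the 48 arrays by group (horizontal axis), with group mean and SD. The lowest array (20760 probes) and the highest (31546) both belong to aCaN, and no difference between groups passed a permutation test.

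Genes for the breakdown of organic contaminants took the largest share of the signal among the categories of the array, 27.9% (mean of 48 arrays), followed by stress response genes with 22.4%, metal resistance genes with 12.6%, carbon cycling genes with 12.3% and nitrogen cycling genes with 8.26%. Bacterial probes held 93.8% of the signal, fungal probes 3.56% and archaeal probes 1.81%. Proteobacteria contributed 57.0% and Actinobacteria 17.7%. These shares follow the design of the array as well as the soil.

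The 2 deposited tables differ in how values and names go together. In the processed table, 99.2% of 35305 matched data lines held the values of another probe of the raw table, and 98.2% carried another family's name. Genus explained 1.29% of the variance between probes there, inside the range of shuffled names, against 6.15% in the raw table. The values below therefore come from the raw table. Over the first 40098 lines of the processed table, the names eCaN and aCeN are exchanged for 24 arrays. The other 24 keep theirs. In its next 5390 lines, all 20132 values stood under the same column name as in the raw table. If the first 40098 lines have the names right, the CO2 and N comparisons below trade places, while the interaction and eCeN against aCaN stay as they are.

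**Figure D2:**
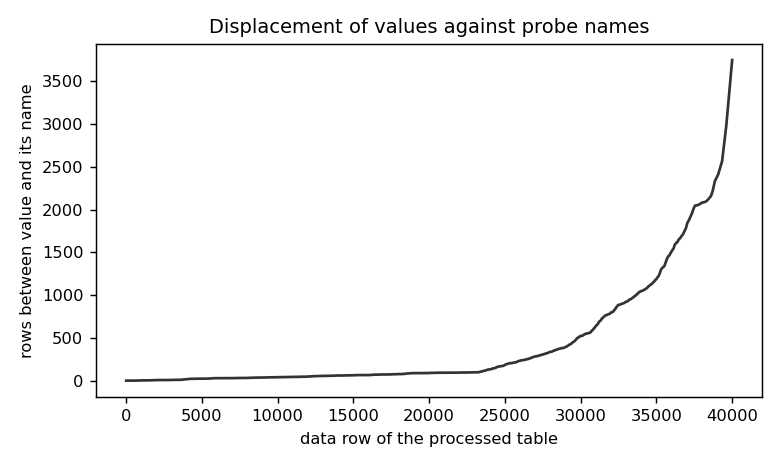
Distance in data lines between a value of the processed table and the line of the raw table it matches (vertical axis), along the processed table (horizontal axis). The distance grows along the table to 3944 lines at the last match.

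A family total adds the signals of all its probes, so it also counts how many of them were detected. The same holds after quantile normalization, where a probe not detected still adds nothing to a total. The mean log2 signal of the detected probes does not add up signals, but it depends on which probes were detected. The array with the fewest detected probes (20760, aCaN 5) had a median detected signal of 16259. The array with the most (31546, aCaN 1) had 10042. A turn of sign on means is therefore not free of the number detected. Summarised by means, the sign turned for 19 of the 27 named families under CO2 at ambient N and for 23 of 28 under N at ambient CO2. The median of all 366 families was 0.01 log2 for CO2 at ambient N on totals and -0.07 on means of detected probes, and for N at ambient CO2 it was 0.03 and -0.08. For eCeN against aCaN, it was 0.02 and -0.12. Each sign below is that of the total, and a sign that turned under another scaling is given beside it.

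The arrays also carried a structure that runs across the groups. Within an N level, arrays of the same number resembled one another. Group-centred log2 signals of aCaN and eCaN arrays with the same number had a mean correlation of 0.28 (SD 0.22, 12 numbers) against -0.02 for different numbers (one-sided permutation p = 0.0011), and those of aCeN and eCeN arrays 0.45 (SD 0.27) against -0.04 (p = 0.0001). Between N levels, arrays of the same number averaged from -0.04 to 0.05 (p from 0.303 to 0.638). The labels give no ring, batch or slide for any array, and with the names of the processed table the resemblance lies within a CO2 level instead. The comparisons below treat the arrays as independent. Fits that take this resemblance into account were added after it was seen, and stand below where they change a call.

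Arrays numbered 10 to 12, which are 3 per group, had a mean correlation of 0.40 with one another (SD 0.19, 54 pairs from different groups), against 0.03 (SD 0.30, 486 pairs) among arrays numbered 1 to 9. The boundary is not sharp: array 10 of eCaN averaged 0.00 with the other arrays 10 to 12 (-0.15 to 0.11), while array 9 of eCeN averaged 0.48 with them and array 9 of aCeN 0.38. Arrays 10 to 12 detected 29092 ± 890 probes (SD, n = 12) against 27067 ± 2356 (n = 36) in the others. These numbers were picked from the same data: 147 of 366 families differed between the sets in limma, but chance is not excluded once same-numbered arrays of an N level are kept together. The split is balanced over the groups, and with a term for it in the model, or without those 12 arrays, limma called 0 families in each comparison below.

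**Figure D3:**
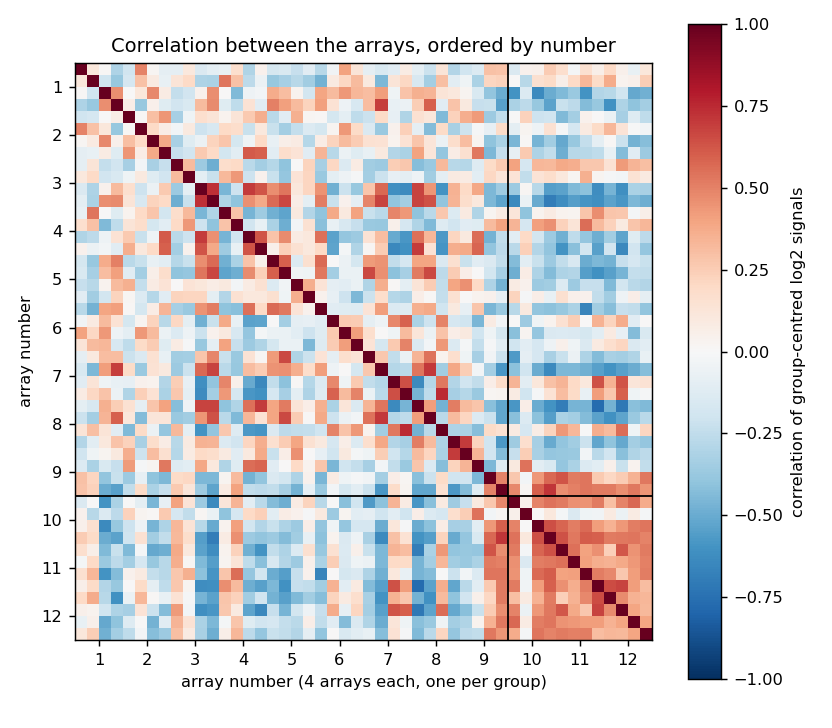
Pearson correlation (colour scale from -1 to 1) between the 48 arrays, ordered by array number on each axis with 4 arrays per number. It was taken over the 8515 probes detected in all arrays, after the group mean of each probe was taken out. Within a number, the 2 arrays of ambient N and the 2 of enriched N stand side by side. Arrays numbered 10 to 12 have a mean correlation of 0.40 over 54 pairs, but array 10 of eCaN stands outside them (mean 0.00) and array 9 of eCeN (0.48) and of aCeN (0.38) correlate with them.

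CO2 at ambient N. The comparison of eCaN with aCaN asks how the gene content of the soil community differed under enriched CO2 where N stayed ambient. The methane gene mcrA, which encodes a subunit of the enzyme that releases methane in methanogens, stood at 0.18 ± 0.07 log2 in eCaN against aCaN (SE, n = 12 and 12), with 11 of 12 eCaN arrays above the aCaN mean, but turned to -0.12 on the mean of detected probes (adjusted p = 0.748). Relative to the median of all families, mcrA was 0.16 on totals and -0.05 on means. The cobalt-zinc-cadmium efflux family czcC stood at -0.14 ± 0.06 with 12 of 12 eCaN arrays below the aCaN mean, and the family the array calls antioxidant at 0.21 ± 0.08 with 11 of 12 above; neither sign turned under any scaling tried (adjusted p = 0.748 for each). TerC, a tellurium resistance family (0.08 ± 0.03, 11 of 12 arrays), and cytochrome (0.09 ± 0.04, 10 of 12) turned to -0.03 and -0.06 on means of detected probes, though relative to the median each stayed positive (adjusted p = 0.748 for each). None of these 5 families passed.

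Over all 366 families, limma called 0, with 22 at an unadjusted p under 0.05 (20 higher and 2 lower in eCaN, 18.3 expected by chance) and a smallest adjusted p of 0.748. The 95% interval of 225 families lay within 1.2-fold, and that of 343 within 1.5-fold. Of the 23 families of the fixed panel present on the array, 17 had a positive and 6 a negative difference (0 and 23 on means of detected probes, 23 and 0 after quantile normalization), and 0 passed adjusted over the list alone (smallest adjusted p 0.240), with 4 at an unadjusted p under 0.05. These were mcrA, nosZ, the nitrous oxide reductase (6.31%, 11 of 12 arrays), dsrA, a sulfite reductase subunit (4.21%, 11 of 12), and gdh, the glutamate dehydrogenase (11.0%, 11 of 12), whose signs all turned on means of detected probes, to -0.12, -0.06, -0.10 and -0.16 log2. The nitrogenase gene nifH differed by 3.25% (10 of 12 arrays, panel-adjusted p = 0.494) and the nitrite reductase gene nirS by 3.97% (12 of 12, 0.255), and both turned on means of detected probes. The urease gene ureC (-1.49%) and the ammonia monooxygenase gene amoA (-2.22%) turned positive under quantile normalization, and the carbon fixation gene rubisco (0.93%) turned negative on means of detected probes, all with intervals that include 0.

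By process, methane cycling showed the largest difference among the 25 lists, 10.4% (adjusted p = 0.411), which turned negative on means of detected probes (-0.09 log2). Of its 3 members, mcrA and mmoX, the soluble methane monooxygenase (0.18 log2, 11 of 12 arrays, turned to -0.10 on means), reached 0.0556 and 0.0659 adjusted over the list alone, and pmoA did not pass either. With the number within the N level as a replicate block, methane cycling passed (0.14 ± 0.04 log2, 9 of 12 pairs, adjusted p = 0.0277, over its alternatives 0.0277 to 0.867), and so did gdh among the families (0.15 ± 0.03, 10 of 12 pairs, 0.0306, over its alternatives 0.0243 to 0.994). In that fit both also passed after quantile normalization (0.20 and 0.26, adjusted p = 0.0435 and 0.0243), where 17 of 25 lists and 2 of 39 taxa did, all higher in eCaN. Neither passed with 1 total per array (adjusted p = 0.135 and 0.149), where gdh still stood at 0.15 log2. On means of detected probes methane cycling and gdh turned to -0.09 and -0.16, as all 17 lists and both taxa turned. The block therefore gives no direction that holds over the scalings. In denitrification (2.29%) 5 of 5 members did not pass, and in assimilatory nitrate reduction (3.59%) 4 of 4 did not, both lists turning to -0.06 on means of detected probes. The nearest member, nasA, an assimilatory nitrate reductase, stood at 7.61% (9 of 12 arrays, 0.0863 adjusted over the list alone) and turned to -0.03. limma called 0 of 25 lists (1 at an unadjusted p under 0.05) and 0 of 39 taxa (1, the green sulfur bacteria of phylum Chlorobi, 5.55%, adjusted p = 0.507, negative on means of detected probes). It called 0 of 26030 probes (1062 at an unadjusted p under 0.05, 742 higher and 320 lower). The 3 probes with the smallest p stood for phn of a Pseudomonas (-0.72 log2), sigma_70 of Candidatus Poribacteria (-0.79) and gyrB of Rubrobacter xylanophilus (0.75), each with an adjusted p of 0.977. eCaN arrays detected 1320 more probes on average (SE 1087, permutation p = 0.240), and log2 total signal differed by 0.004 (p = 0.884).

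CO2 at enriched N. The comparison of eCeN with aCeN puts the same question where N was added. The 5 families with the smallest p were all lower in eCeN on totals, 2 of them turning on means of detected probes and 1 under quantile normalization. cydA, a subunit of the cytochrome bd oxidase used at low oxygen, stood at -10.6% (-0.16 ± 0.06 log2, SE, n = 12 and 12, 11 of 12 eCeN arrays below the aCeN mean), and trzE at -7.64% (10 of 12), but both turned positive on means of detected probes (0.04 and 0.05). Relative to the median of all families those means were 0.07 and 0.08. The catalase katE stood at -3.55% (10 of 12), which turned to 0.01 under quantile normalization. adpB (-0.38 ± 0.17, 10 of 12) and the drug_resistance_transporter family (-0.24 ± 0.11, 9 of 12) kept their sign under every scaling tried. All 5 had an adjusted p of 0.988.

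Over all families limma called 0 of 366, with 5 at an unadjusted p under 0.05 (18.3 expected by chance), and 249 intervals lay within 1.2-fold. In the panel 13 differences were positive and 10 negative (0 and 23 on means of detected probes, 22 and 1 after quantile normalization), with 0 passing adjusted over the list alone (smallest adjusted p 0.966) and 0 at an unadjusted p under 0.05. Here mcrA differed by 4.58% and nifH by 0.31%, which turned to -0.07 each on means of detected probes. nosZ (-0.06%) and ureC (-2.39%) turned positive under quantile normalization, and gdh (-4.28%) with the processed values put back on their lines (0.01). Of the 25 lists, 19 stood lower and 6 higher in eCeN on totals, but 25 and 0 on means of detected probes, 12 and 13 with 1 total per array, 1 and 24 after quantile normalization and 2 and 23 with the processed values put back on their lines, and methane cycling was at 3.02% (-0.07 log2 on means of detected probes). limma called 0 of 25 lists, 0 of 39 taxa (0 at an unadjusted p under 0.05 in both cases) and 0 of 26030 probes (466). The leading probes stood for Catechol of a Bradyrhizobium (-0.70 log2), pstB of Nitrobacter hamburgensis (0.80) and Tet of a Rhizobium (-0.76), each with an adjusted p of 1.00. Detected probes differed by 802 (SE 724, permutation p = 0.281) and log2 total signal by -0.017 (p = 0.317).

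N at ambient CO2. The comparison of aCeN with aCaN asks how added N alone went with the gene content. dsrB, which encodes the beta subunit of the dissimilatory sulfite reductase of sulfate-reducing microbes, was 8.00% higher in aCeN (0.11 ± 0.04 log2, SE, n = 12 and 12), with 11 of 12 aCeN arrays above the aCaN mean, but turned to -0.06 on means of detected probes. Adjusted over the list alone, it passed within sulfur cycling (adjusted p = 0.0247, 1 of 6 members, the other 5 did not), but not over all 366 families (0.501). Relative to the median of all families it was 0.08 on totals and 0.01 on means. trzE was 12.1% higher (12 of 12 arrays, adjusted p = 0.397) and turned to -0.09 on means of detected probes, -0.01 relative to the median. TerC (7.82%, 11 of 12, adjusted p = 0.397) and cytochrome (6.60%, 9 of 12, 0.787) turned to -0.02 and -0.08, and nbzB stood at -0.66 ± 0.23 (9 of 12, 0.516) with no turn.

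At the level of processes 24 of 25 lists stood higher in aCeN, but 12 did with 1 total per array and 0 on means of detected probes. The lists with an unadjusted p under 0.05 were cellulose degradation (5.13%), sulfur cycling (5.38%) and oxidative and osmotic stress response (4.14%), each with an adjusted p of 0.126, bacteriophage (6.16%, 0.152) and fungi (4.52%, 0.167), which turned to -0.08, -0.08, -0.07, -0.07 and -0.08 log2 on means of detected probes. limma called 0 of 25. In cellulose degradation 4 of 4 members did not pass, exoglucanase being the nearest (9.93%, 10 of 12 arrays, 0.0950 adjusted over the list alone, -0.07 on means). In oxidative and osmotic stress response 9 of 9 members did not pass, with katE at 4.21% (11 of 12, 0.137, -0.05 on means).

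limma called 0 of 366 families, with 16 at an unadjusted p under 0.05 (13 higher and 3 lower) and 230 intervals within 1.2-fold. In the panel 19 differences were positive and 4 negative (0 and 23 on means of detected probes, 13 and 10 with 1 total per array), and 0 passed adjusted over the list alone (smallest adjusted p 0.506). dsrA was the only panel family with an unadjusted p under 0.05 (4.51%, 10 of 12 arrays), and it turned to -0.09 on means of detected probes. gdh differed by 9.55%, amoA by 4.94% and nifH by 3.63%, turning to -0.12, -0.06 and -0.08. limma called 0 of 39 taxa (4 at an unadjusted p under 0.05): Chlamydiae 19.3% (adjusted p = 0.161), Chloroflexi 6.20% (0.161), Ascomycota 4.72% (0.407) and Fungi 4.52% (0.407), of which the last 3 turned negative on means of detected probes. Of 26030 probes it called 0 (1688 at an unadjusted p under 0.05, 531 higher and 1157 lower), led by catB of a Burkholderia (-0.97 log2), phn of a Burkholderia (-0.91) and limEH of Nocardia farcinica (0.69), each with an adjusted p of 0.467. The share of lower probes among those with an unadjusted p under 0.05 was 68.5%, but 43.9% after quantile normalization. Detected probes differed by 485 (SE 1122, permutation p = 0.670) and log2 total signal by 0.032 (p = 0.191).

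**Figure D4:**
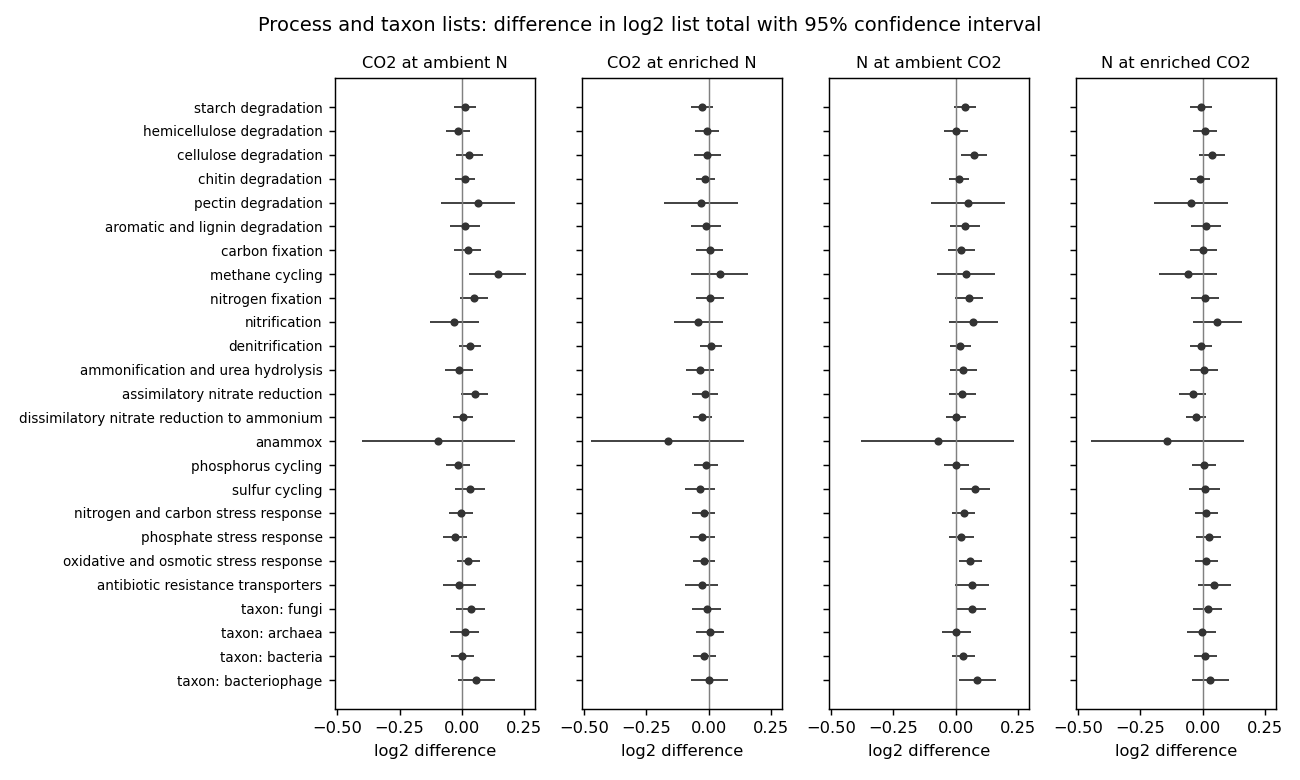
Difference in log2 list total (horizontal axis, points with 95% confidence intervals, 12 arrays per group) for the 25 process and taxon lists in the 4 comparisons of single factors. Under N at ambient CO2, 24 of 25 points lie to the right of 0, though 24 of the 25 signs turned on means of detected probes and 12 with 1 total per array, and limma called 0 lists in each comparison.

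N at enriched CO2. The comparison of eCeN with eCaN asks the same of added N under enriched CO2. mmoX, the soluble methane monooxygenase with which some bacteria oxidise methane, was 17.3% lower: its difference was -0.27 ± 0.09 log2 (SE, n = 12 and 12), and 11 of 12 eCeN arrays lay below the eCaN mean. Adjusted over the list alone it passed within methane cycling (adjusted p = 0.00711, 1 of 3 members, while mcrA and pmoA did not), but over all families it did not (0.591). Its sign did not turn under any scaling tried, although relative to the median it shrank from -0.28 on totals to -0.05 on means of detected probes. Without eCeN array 8 it was -0.33 with an adjusted p of 0.0367 over all families. ABC_transporter_II (-0.30 ± 0.10, 10 of 12 arrays, adjusted p = 0.591), tphA, named for terephthalate breakdown (-0.36 ± 0.13, 10 of 12, 0.882), and mdlB, named for mandelate breakdown (-0.18 ± 0.07, 11 of 12, 0.882), also kept their sign under every scaling tried. proW, part of an uptake system for osmoprotectants, stood at 0.33 ± 0.13 (10 of 12, 0.882) and turned to -0.13 on means of detected probes.

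limma called 0 of 366 families, with 16 at an unadjusted p under 0.05 (9 higher and 7 lower in eCeN) and 231 intervals within 1.2-fold. In the panel 14 differences were positive and 9 negative (1 and 22 on means of detected probes, 10 and 13 with 1 total per array), with 0 passing adjusted over the list alone (smallest adjusted p 0.972) and 0 at an unadjusted p under 0.05. There amoA differed by 4.06% and gdh by -5.50%, which turned to -0.02 and 0.02 on means of detected probes, nosZ by -2.23%, which turned with the processed values put back, and mcrA by -3.24%. Methane cycling stood at -4.01% and nitrification at 4.06% (-0.03 log2 on means), and limma called 0 of 25 lists (0 at an unadjusted p under 0.05). It called 0 of 39 taxa (3 at an unadjusted p under 0.05): Bacteroidetes 4.32%, Chlamydiae 17.7% and Fusobacteria 32.5%, each with an adjusted p of 0.270, of which Bacteroidetes and Chlamydiae turned negative on means of detected probes. Of 26030 probes it called 0 (1557 at an unadjusted p under 0.05, 407 higher and 1150 lower). The leading probes stood for napA of an unnamed organism (-0.91 log2), Catechol of a Marinobacter (-0.91) and proO of Magnetospirillum magneticum (-0.66), each with an adjusted p of 0.759. Detected probes differed by -32.9 (SE 668, permutation p = 0.96) and log2 total signal by 0.011 (p = 0.543).

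**Figure D5:**
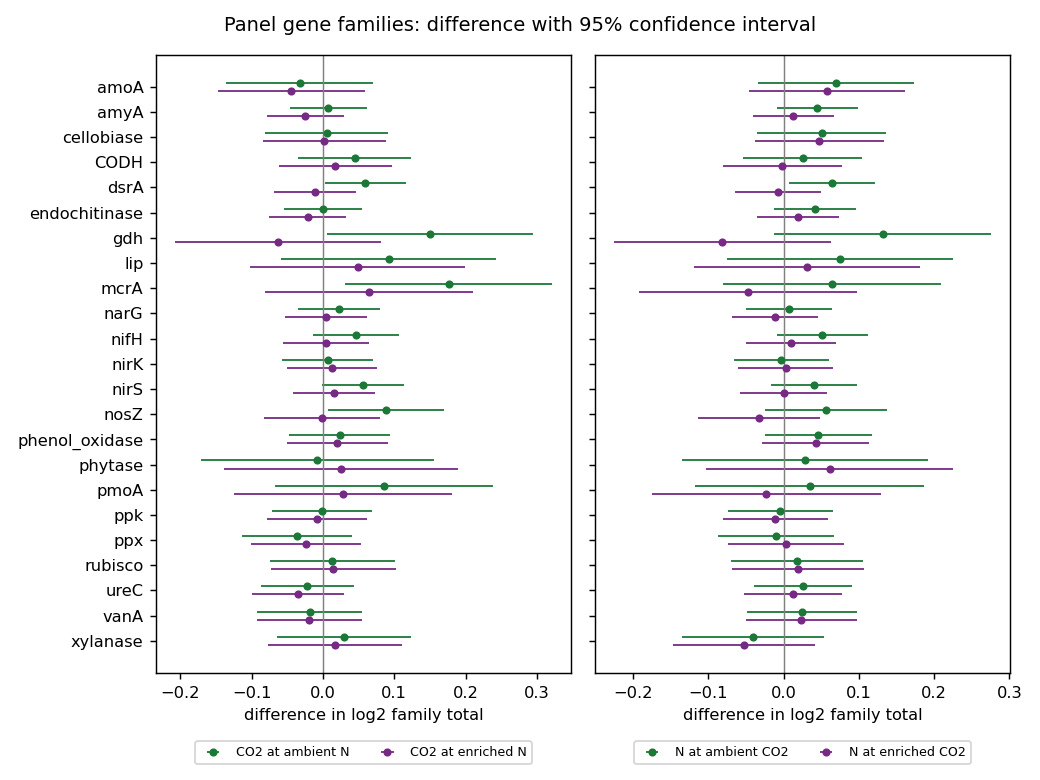
Difference in log2 family total (horizontal axis, points with 95% confidence intervals, 12 arrays per group) for the 23 panel families, for CO2 at each N level (left) and N at each CO2 level (right). Before adjustment, the intervals of mcrA, nosZ, dsrA and gdh for CO2 at ambient N, and of dsrA for N at ambient CO2, lie to the right of 0. All of these signs turned on means of detected probes, and 0 families passed adjusted over the list alone.

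Interaction of CO2 and N. The series asks in its title whether responses to CO2 depend on N, and the interaction (CO2 effect at enriched N minus CO2 effect at ambient N) tests that difference itself. The enzyme gene gdh, which links ammonium to glutamate, had the smallest p of the panel: its CO2 effect was 13.7% lower at enriched N, an interaction of -0.21 ± 0.10 log2 (SE, 48 arrays, adjusted p = 0.998, 0.940 over the panel) that turned to 0.14 on means of detected probes. With the number within the N level as a replicate block it passed over all families (-0.21 ± 0.04, adjusted p = 0.0289, over its alternatives 0.0289 to 1.00), but in that fit it did not pass with 1 total per array (0.217), after quantile normalization (0.448) or on means of detected probes (0.965). In that order the interaction of gdh was -0.19, -0.28 and 0.14 log2. Among all families trzE led with -0.19 ± 0.07, followed by nitrogen_fixation_genes (-0.57 ± 0.24), cytochrome (-0.12 ± 0.05) and the phage families scaffold (-0.28 ± 0.12) and endolysin_transglycosylase (-0.26 ± 0.12), each with an adjusted p of 0.998, of which trzE and cytochrome turned on means of detected probes, to 0.11 and 0.01. For mcrA the interaction was -0.11 ± 0.10 (p = 0.280) and for nosZ -0.09 ± 0.06 (p = 0.125), both positive on means of detected probes, so that their CO2 differences were not shown to depend on N.

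limma called 0 of 366 families for the interaction (9 at an unadjusted p under 0.05, all 9 negative) and 181 intervals lay within 1.2-fold. In the panel 19 interactions were negative and 4 positive (0 and 23 on means of detected probes, 11 and 12 with 1 total per array), and 0 passed adjusted over the list alone. Of the 25 lists 22 were negative, but 2 were on means of detected probes, 16 with 1 total per array and 25 after quantile normalization. Methane cycling stood at -6.66% (0.03 log2 on means) and assimilatory nitrate reduction at -4.49%, which did not turn, and limma called 0 lists, 0 of 39 taxa (0 at an unadjusted p under 0.05 in both cases) and 0 of 26030 probes (696). The leading probes stood for sigma_70 of Candidatus Poribacteria (1.32 log2), glnA of Mycobacterium vanbaalenii (-0.98) and ahpF of Slackia heliotrinireducens (-1.07), each with an adjusted p of 1.00. For detected probes the interaction was -518 (SE 1306, permutation p = 0.697) and for log2 total signal -0.021 (p = 0.482).

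The process lists can be set side by side over the 4 comparisons of single factors, in the order CO2 at ambient N, CO2 at enriched N, N at ambient CO2 and N at enriched CO2. Among polymers, starch degradation differed by 0.89%, -2.03%, 2.55% and -0.42%, hemicellulose degradation by -1.07%, -0.48%, 0.13% and 0.73%, cellulose degradation by 2.01%, -0.45%, 5.13% and 2.59%, chitin degradation by 0.76%, -0.97%, 0.91% and -0.82%, pectin degradation by 4.43%, -2.23%, 3.31% and -3.28%, and aromatic and lignin degradation by 0.78%, -0.81%, 2.52% and 0.91%. Carbon fixation differed by 1.56%, 0.17%, 1.56% and 0.17%. Within the nitrogen cycle, nitrogen fixation differed by 3.25%, 0.31%, 3.63% and 0.69%, nitrification by -2.17%, -2.97%, 4.92% and 4.06%, denitrification by 2.29%, 0.54%, 1.26% and -0.46%, ammonification and urea hydrolysis by -0.82%, -2.49%, 2.13% and 0.42%, assimilatory nitrate reduction by 3.59%, -1.06%, 1.74% and -2.82%, dissimilatory nitrate reduction to ammonium by 0.22%, -1.80%, 0.14% and -1.89%, and anammox by -6.39%, -10.8%, -4.89% and -9.35%. Phosphorus cycling differed by -1.06%, -0.83%, 0.17% and 0.40%, and sulfur cycling by 2.19%, -2.56%, 5.38% and 0.48%. Of the stress lists, the nitrogen and carbon stress response differed by -0.29%, -1.45%, 2.18% and 0.99%, the phosphate stress response by -1.92%, -1.86%, 1.56% and 1.62%, and the oxidative and osmotic stress response by 1.74%, -1.36%, 4.14% and 0.96%. Antibiotic resistance transporters, a list that also holds the B_lactamase and Van families, differed by -0.70%, -1.99%, 4.58% and 3.22%. By taxon, fungi differed by 2.47%, -0.65%, 4.52% and 1.34%, archaea by 0.72%, 0.27%, 0.11% and -0.33%, bacteria by 0.13%, -1.23%, 2.13% and 0.74% and bacteriophage by 4.04%, 0.06%, 6.16% and 2.11%. Adjusted over the list alone, mmoX under N at enriched CO2 and dsrB under N at ambient CO2 passed, and 0 members of the other lists did. Each list was adjusted by itself in each comparison, so some passes can arise by chance alone. Of the 25 signs in each comparison, 17, 6, 24 and 16 turned on means of detected probes, 2, 7, 12 and 7 with 1 total per array, 7, 18, 0 and 8 after quantile normalization, and 8, 17, 1 and 6 with the processed values put back on their lines. Over these scalings together 25, 24, 25 and 23 turned at least once, so these percentages give no direction by themselves.

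Both factors together. eCeN against aCaN, a comparison added after the data were examined, gave TerC at 7.89% (0.11 ± 0.03 log2, SE, 12 of 12 eCeN arrays above the aCaN mean, adjusted p = 0.728) as the family with the smallest p. The chaperonin groEL followed with 9.13% (11 of 12), then cydB, a subunit of the cytochrome bd oxidase, with 8.93% (10 of 12), pbrT, named for lead uptake, with 29.0% (9 of 12) and the drug_resistance_transporter family with -17.3% (9 of 12), each with an adjusted p of 0.933. TerC, groEL, cydB and pbrT turned on means of detected probes, to -0.10, -0.12, -0.17 and -0.17 log2, and the drug_resistance_transporter family did not. limma called 0 of 366 families, with 15 at an unadjusted p under 0.05 (10 higher and 5 lower). In the panel 0 passed adjusted over the list alone (smallest adjusted p 0.373).

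Each factor over both levels of the other. Pooling 24 against 24 arrays was added after the planned comparisons had given 0 calls. For N, probes of Chlamydiae, a phylum of bacteria that live inside other cells, were 18.5% higher at enriched N (0.24 ± 0.07 log2, SE, adjusted p = 0.0188 over 39 taxa), and limma called this 1 of 39 taxa, with 6 at an unadjusted p under 0.05. Its total rested on 42 probes of 19 families, of which an array detected 8 to 17, and averaged 183132 in aCaN, 176131 in eCaN, 220377 in aCeN and 208501 in eCeN, with 10 of 12 aCeN and 12 of 12 eCeN arrays above the ambient N mean against 7 and 3 of 12. On means of detected probes the difference shrank to 0.01 (adjusted p = 0.946), and without arrays 10 to 12 the call ended (0.25, adjusted p = 0.117). It also ended when each 2 arrays of the same number and N level were averaged (0.24, adjusted p = 0.0520, and 0.0880 to 0.951 over 3 other scalings), since 24 arrays then count as 12. With the names of eCaN and aCeN exchanged, the difference belonged to CO2, and N gave -0.05 (adjusted p = 0.794). Bacteroidetes (3.81%, adjusted p = 0.0692) and Chloroflexi (4.29%, 0.0776) did not pass and turned to -0.04 and -0.06 on means of detected probes. limma called 0 of 366 families for N (35 at an unadjusted p under 0.05, smallest adjusted p 0.340) and 0 for CO2 (12, 0.904), 0 of 25 lists for either factor (5 and 1), 0 of 39 taxa for CO2 (1) and 0 of 26030 probes (2676 and 781). For CO2, mcrA was 8.70% higher (adjusted p = 0.904) and methane cycling 6.64% (0.663), and both turned on means of detected probes, to -0.09 and -0.08. With the number within the N level as a replicate block, 0 lists passed for CO2 on the signals as deposited (methane cycling nearest, 16 of 24 pairs, adjusted p = 0.0578, over its alternatives 0.0338 to 0.931) and 16 after quantile normalization, all of which turned on means of detected probes.

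Community composition as a whole was compared with PERMANOVA on Bray-Curtis distances over all probes. CO2 accounted for 2.20% of the variation among the 48 arrays (permutation p = 0.362), N for 2.83% (p = 0.182) and their interaction for 1.37% (p = 0.806). With permutations confined to same-numbered arrays of an N level (a replicate block added after their resemblance was seen), p was 0.0274 for CO2 and 0.395 for the interaction, and with whole pairs permuted it was 0.408 for N. In the same test the p for CO2 was 0.00721 on presence and absence, 0.0109 on Hellinger-transformed signals, 0.0251 with 1 total per array and 0.00269 with the processed values put back on their lines, but 0.164 on log2 signals of the probes detected in all arrays. At ambient N alone it was 0.0664 on Bray-Curtis distances and, in the same order, 0.0483, 0.0469, 0.0591, 0.00928 and 0.187. At enriched N alone it was 0.276, 0.282, 0.288, 0.296, 0.0396 and 0.462. Each of these distances, except the one on log2 signals, also counts which probes were detected. Arrays at enriched CO2 detected on average 1320 more probes at ambient N and 802 more at enriched N. The lower p-values are thus not free of the number detected. The processed values put back had been filtered group by group by the authors, which can itself make presence differ between groups. Permuting the labels afterwards does not redo that filter. The p-values of the values put back (0.00269, 0.00928 and 0.0396) therefore cannot decide whether composition differed with CO2. Pairs of arrays within a group lay 0.258 apart on average (264 pairs), as did pairs from different groups (0.258, 864 pairs). The 4 single-factor pairs of groups gave 4.72%, 2.64%, 4.04% and 4.58%, in the order used above, with adjusted p from 0.604 to 0.827, and the spread within groups did not differ by the permutation test (p = 0.397). In a test of detection itself, Fisher's exact test called 0 probes in each comparison, with 325, 160, 208 and 254 at an unadjusted p under 0.05.

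Planted changes show what this number of arrays could have detected when many features change at once and the arrays are independent. Over 20 runs, 300 families, 40 lists and 1000 probes were planted at each fold. Recovery when only few features change was not tested, and the adjustment is stricter there. With the arrays of the CO2 comparison at ambient N shuffled and changes planted, limma recovered 35% of families at 1.1-fold, 63.7% at 1.2-fold and 91% at 1.5-fold. For lists it recovered 80% at 1.1-fold and 100% at 1.2-fold, and for single probes 21.7% at 1.5-fold and 78.5% at 2-fold.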

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

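The counts given here were chosen after the last part of the tables was seen. It holds 23243 values, a signal in data that the comparisons did not use, between 6.30 and 9.25, in 8 of the 48 array columns, against linear signals of 1091 and more in the lines above it. They stand in 6009 lines, with 2224 to 3304 values per column and column medians between 7.26 and 7.56. The lines name 413 gene families, 8 of which occur only there. Their scale and the arrays they belong to are not given by the labels, and no explanation, technical or biological, was tested.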

How the results depend on the processing

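Tests with names exchanged, with processed values put back on their lines, with arrays 10 to 12 left out or given a term, of lists after quantile normalization, of taxa with 1 total per array, after quantile normalization or on means of detected probes, of eCeN against aCaN, of pooled factors, and with the number within the N level as a replicate block or as means were chosen after the data had been seen, the rest beforehand. Over the settings run for each, the 5 planned comparisons gave 0 families, lists, taxa and probes in limma, and composition gave 0 terms and pairs past the threshold, with exceptions from 1 array left out and from 1 block. Without eCeN replicate 8, families under N at enriched CO2 went from 0 to 1: mmoX stood at -0.33 (adjusted p = 0.0367, over its alternatives 0.0367 to 0.996), and the cause was not tested.

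Over all groups 3 of 48 arrays correlated best with their own number. Within an N level, 3 of 12 aCaN arrays correlated best with the eCaN array of their number and 7 of 12 aCeN arrays with the eCeN array. In the other direction, 1 of 12 eCaN and 5 of 12 eCeN arrays did. Of the correlations between same-numbered arrays, 9 and 11 of 12 exceeded 0.1, a hint from the data and not from the design. With the number within the N level as a replicate block, gdh passed under CO2 at ambient N (1 family, 0.15, adjusted p = 0.0306, over its alternatives 0.0243 to 0.994) and for the interaction (1 family, -0.21, adjusted p = 0.0289, over its alternatives 0.0289 to 1.00), methane cycling under CO2 at ambient N (1 list, 0.14, adjusted p = 0.0277, over its alternatives 0.0277 to 0.867), and CO2 in composition (1 term, 2.20%, p = 0.0274). For composition at ambient N alone, the permutation p was 0.0664 on Bray-Curtis distances, 0.0591 with 1 total per array and 0.187 on log2 signals. Only the last of these, over probes detected in all arrays, does not count which probes were detected. It was 0.0483 on presence and absence, 0.0469 on Hellinger-transformed signals and 0.00928 with the processed values put back. At enriched N alone only the last was under 0.05 (0.0396, the others 0.276 to 0.462). The processed values had been filtered group by group before the labels were permuted, so 0.00928 and 0.0396 cannot decide on CO2. With quantile normalization as well, that block gave 17 lists for CO2 at ambient N (0.07 to 0.20, adjusted p = 0.0435 to 0.0493) and 16 for pooled CO2 (0.05 to 0.14, 0.0338 to 0.0422), 1 family for CO2 at ambient N (gdh, 0.26, 0.0243), 2 taxa there (Chlorobi 0.14 and Planctomycetes 0.11, both 0.0303) and 1 for pooled CO2 (Chlorobi, 0.09, 0.0461), and the cause was not tested. With 1 total per array or on means of detected probes it gave 0 families, lists and taxa, and all 17 and all 16 lists turned negative on those means. Of these 17 and 16 lists, 2 and 6 had the other sign on the signals as deposited, and 3 and 3 with 1 total per array. By construction the block leaves the differences as they were and changes only their error. Averaging those arrays took taxa under pooled N from 1 to 0, as it did with 1 total per array, quantile normalization and means of detected probes (Chlamydiae 0.24, 0.22, 0.26 and 0.01, adjusted p = 0.0520, 0.0880, 0.179 and 0.951). Neither of these, nor the replicate block over all groups, changed another call except under pooled N below.

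Families with an unadjusted p under 0.05 numbered 13 to 110 for CO2 at ambient N, 3 to 17 for CO2 at enriched N, 7 to 29 for N at ambient CO2, 5 to 25 for N at enriched CO2, 2 to 18 for the interaction and 9 to 46 for eCeN against aCaN over the settings other than single arrays left out. With single arrays left out they moved as follows, and every array that moved a count by over 1.5 times is named with the count without it. For CO2 at ambient N 22 became 5 to 32: aCaN 5 (5), aCaN 6 (7), eCaN 3 (14), eCaN 4 (11). For CO2 at enriched N 5 became 3 to 10: aCeN 1 (3), aCeN 2 (9), aCeN 3 (9), aCeN 4 (8), aCeN 10 (10), aCeN 11 (8), aCeN 12 (8), eCeN 1 (9), eCeN 3 (8), eCeN 7 (8), eCeN 10 (3), eCeN 12 (3). For N at ambient CO2 16 became 11 to 29: aCaN 3 (25), aCaN 10 (25), aCaN 11 (29), aCeN 3 (26). For N at enriched CO2 16 became 12 to 25: eCeN 8 (25). For the interaction 9 became 5 to 14: aCaN 6 (5), aCeN 4 (14). For eCeN against aCaN 15 became 7 to 23: aCaN 3 (23), aCaN 5 (8), aCaN 6 (9), aCaN 7 (7). For pooled CO2 12 became 7 to 19: aCaN 2 (19), aCaN 9 (19), eCaN 1 (7), aCeN 4 (7). For pooled N 35 became 27 to 43, no array moving it so far. The cause was not tested.

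With the replicate block, 1 family passed under pooled N (cydB, 0.12, adjusted p = 0.0239, over its alternatives 0.0239 to 0.999). Taxa under pooled N went from 1 to 3 with the replicate block, to 3 with a term for arrays 10 to 12, to 0 on means of detected probes, to 0 without arrays 10 to 12 and to 0 with processed values put back on their lines. Leaving out single arrays gave 1 to 3: 3 without aCaN 10 or eCeN 4, and 2 without aCaN 3, 6 or 7, aCeN 2 or 10, or eCeN 2. The taxa that joined were Bacteroidetes and Chloroflexi. After quantile normalization the 1 taxon was Fusobacteria (0.36, adjusted p = 0.0381, over its alternatives 0.0381 to 0.827) and not Chlamydiae, whose difference was no smaller (0.26 against 0.24, adjusted p = 0.0524, over its alternatives 0.00439 to 0.951). For these the cause was not tested. Exchanging the names makes the N contrast the CO2 contrast by construction: it gave 1 taxon for pooled CO2, 0 for pooled N, Chlamydiae reversed at -0.0516 for N, detected probes of -32.9 for CO2 and 802 for N at the enriched level of the other factor, and log2 total signal of 0.0109 and -0.0173 there. Processed values put back on their lines gave a log2 total signal of 0.0253 for CO2 at enriched N, and the cause was not tested. normexp was not run, for want of background values, so how far signal over background limits dim probes was not analysed here.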

Other observations

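The splits of the planned comparisons, of eCeN against aCaN and of taxa that pass under N, the test of opposed CO2 responses, the orders of the numbers and every test that keeps same-numbered arrays of an N level together or exchanges them were chosen after the result was seen; the pooled factors and the contrast of arrays 10 to 12 with the others were themselves chosen after the data had been seen.

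The first pattern is that arrays of the same number resemble one another within an N level (excess correlation 0.39 over different numbers), and that arrays 10 to 12, picked from the same data, do so across groups (0.38 over arrays 1 to 9). An array-wide difference in signal distribution and a brightness trend are argued against for both, since 96.6% (jackknife SE 2.2) and 95.6% (SE 1.4) of the first excess and 101.2% (SE 4.2) and 91.3% (SE 1.9) of the second were left after each was removed, as were 90.6% (SE 4.0) and 91.6% (SE 3.7) of the excess of the same number over all groups together. These correlations used only the 8515 probes detected in all arrays, so the argument covers those. The number of detected probes may account for part of the first (62.2% left, SE 9.5). With that SE, it is not excluded that it accounts for most of the first. It cannot be told apart from the second (46.8% left, SE 10.5, while 59.9% of the families still passed with it in the model, SE 51.5) or from the excess over all groups (55.7% left, SE 26.5). Of 100 orders of the numbers within groups 1 had a choice of 3 numbers that gave as many families (real 147, highest other 98), but with same-numbered arrays of an N level kept together 6 did (highest other 170), so for arrays 10 to 12 chance is not excluded beyond the first resemblance. The labels give no ring, plot neighbourhood or laboratory batch, so what lies behind the first was not tested, and no biological explanation was tested. By the names of the raw table the resembling pairs differ in CO2, and by those of the processed table in N. Which names are right is not decided here.

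The second pattern is that more probes were lower than higher under enriched N, 68.5% of those with an unadjusted p under 0.05 at ambient CO2 and 73.9% at enriched CO2. Of 100 splits, 3 gave as high a mean share (real 71.2%, highest other 72.7%), but with same-numbered arrays of an N level kept together 8 did (highest other 79.8%), so chance is not excluded. After quantile normalization the shares were 43.9% and 54.4%, while with 1 total per array they were 78.8% and 78.2%. That is consistent with a difference in the distribution of signals over the whole array. Whether N itself altered that distribution was not tested.

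The third pattern is how the CO2 effects at both N levels relate across 366 families, which are not independent replicates. Their correlation was 0.25, and 19 of 100 regroupings gave as high a value (highest other 0.58), so a response shared by both N levels is not shown. Of the families, 64.5% had a negative interaction, and 12 of 100 splits gave as high a share (highest other 70.8%), so opposed responses are not shown either, and on means of detected probes the median interaction turned from -0.02 to 0.04. Both draws treat same-numbered arrays of an N level as independent, and none that keeps them together was run for this pattern.

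For the comparisons themselves, the number of 100 splits that gave as many results with an unadjusted p under 0.05 tells whether chance can be excluded. For families it was 26 for CO2 at ambient N (real 22, highest other 91), 83 for CO2 at enriched N (5, 89), 54 for N at ambient CO2 (16, 165), 27 for N at enriched CO2 (16, 83), 62 for the interaction (9, 97) and 47 for eCeN against aCaN (15, 88). For lists it was 54 for CO2 at ambient N (1, 11) and 9 for N at ambient CO2 (5, 13), and for taxa 52 for CO2 at ambient N (1, 12), 25 for N at ambient CO2 (4, 14) and 20 for N at enriched CO2 (3, 9). The other planned comparisons had 0 such lists or taxa, which every split reaches, so nothing was tested there. In the order of the 5 planned comparisons it was, for probes, 35 (1062, 5161), 91 (466, 6985), 32 (1688, 9686), 24 (1557, 5711) and 59 (696, 7801). With each factor pooled it was 53 for CO2 (12, 72) and 17 for N (35, 108) in families, and 57 (1, 13) and 9 (5, 10) in lists. Chance is excluded for none of the counts tested. Splits that call several times the real count point to a structure of the samples other than the groups, or to families and probes that vary together, which these splits do not tell apart.

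With the number within the N level as a replicate block, arrays were exchanged within pairs 100 times, the real arrangement included. For families with an unadjusted p under 0.05, 9 gave as many for CO2 at ambient N (real 43, highest other 69), 29 for CO2 at enriched N (14, 22), 44 for the interaction (17, 46) and 9 for pooled CO2 (32, 46). For lists it was 29 for CO2 at ambient N (3, 11), 51 for the interaction (1, 7) and 48 for pooled CO2 (1, 9), with 0 lists for CO2 at enriched N and so no test. In the order of the families it was 57 (2, 10), 60 (1, 3), 24 (3, 6) and 3 (5, 5) for taxa, and 8 (2546, 4409), 47 (920, 2887), 41 (1291, 3315) and 11 (2021, 3532) for probes. For the 1 family that passed for CO2 at ambient N, gdh, 10 exchanges gave as many (highest other 4), and for the 1 list, methane cycling, 8 did (highest other 7), so chance is not excluded for either. For the 1 family of the interaction, again gdh, 2 did (highest other 1). These exchanges take CO2 to have no effect at either N level, so they do not test an interaction by itself. For the taxa under pooled CO2, 3 exchanges gave as many with an unadjusted p under 0.05, of which 0 passed the adjustment. Such low counts are few among many tests chosen after the result was seen, so chance is not excluded. Whether CO2 changed gdh differently at the N levels was tested no further, and its sign turned on means of detected probes. After quantile normalization in the same fit, 2 exchanges gave as many lists for CO2 at ambient N (real 17, highest other 24) and 2 for pooled CO2 (16, 22), 7 as many families for CO2 at ambient N (1, 49), and 5 and 3 as many taxa for CO2 at ambient N (2, 8) and pooled CO2 (1, 4). Few exchanges reached the counts of lists and of the taxon under pooled CO2, in this scaling alone. The lists overlap, with bacteria alone at 93.8% of the signal. A total after quantile normalization also follows the number of detected probes, since a probe not detected adds nothing to it. The median of all families there was 0.09 and 0.04 log2 for CO2 at ambient and at enriched N. For N at ambient and at enriched CO2 it was 0.04 and -0.001. In that order, the groups differed by 1320, 802, 485 and -32.9 detected probes. This fit and scaling were chosen after the data were seen, so chance is not excluded for these counts either. All these lists and taxa turned on means of detected probes. A difference in the number of detected probes, or in how signal is spread over the array, is therefore not told apart from a difference in gene content.

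For taxa that pass under pooled N, 4 of 100 splits gave as many (real 1, highest other 4), but these splits treat same-numbered arrays of an N level as independent. On means of those arrays 0 taxa passed, and 6 of 100 splits of the pairs gave as large an absolute t for any taxon (real 3.64, highest other 4.47), so chance is not excluded. The Chlamydiae difference was 0.24 log2 on totals and 0.26 after quantile normalization, where it did not pass (adjusted p = 0.0524, over its alternatives 0.00439 to 0.951) although it was no smaller. On means of detected probes it was 0.01, and with the names of eCaN and aCeN exchanged it was -0.05.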
